A study of Escherichia coli with 6 samples.

How the data were processed

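The series compared Escherichia coli K-12 MG1655 cells carrying the Csp231I restriction-modification system on a plasmid derived from pBR322, in the complete form or as a variant, together with a second plasmid that supplies further methyltransferase. Per the labels' protocols, cells grown in LB were collected in mid-logarithmic phase, total RNA was extracted from 2 biological replicates per group, rRNA was depleted with Ribo-Zero and libraries were made by Illumina protocols; whether they keep strand was not given in the sources used here. Groups were taken from the labels: 6 libraries in 3 groups of 2. Per the submitters' processing notes, BWA 0.7.17-r1188, SAMtools 1.6 and Cuffdiff were used, the last with no version given. The file used here is a gene table of Cuffdiff output with 4504 genes, 6 of them on the plasmid, and 3 comparisons.

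FPKM values (fragments per kilobase of gene, scaled to the number of fragments mapped) were computed by the authors, 1 value per group, per the file headers. The deposited log2 fold changes are the ratio of these values; recomputed ones differed by at most 4.96e-05. The deposited test statistic is a score made by the authors' Cuffdiff run. The deposited p-values and q-values come from the same run, and q was checked to equal the Benjamini-Hochberg adjustment over all 13089 tested rows of the 3 comparisons together (largest difference 5.28e-07). The lowest p-value was 5e-05, held by 40.3% of tested rows, so these rows cannot be ranked by p. The median absolute test statistic at q-values of 0.04 to 0.06 was 1.54, lower than a normal p-value would need; the simulations called genes beyond it, but in the table called and uncalled genes overlap in this statistic. No test across libraries was run here, because no value per library was used, and the depth of each library is unknown. A group value of 0 is reported as listed at 0, with no fold.

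From the table, an implied SE was computed per gene and comparison as the log2 fold change over the test statistic, and 1 variance per group was solved from the 3 SEs. Negative variances arose in 0 of 4314 genes. At 10 to 100 FPKM the median implied SD of a group value was 0.146 on the log2 scale in WT, and above 10000 FPKM it was 0.679, so very abundant RNAs pass the test less readily. These SEs are what the authors' software gave and were not checked against single libraries. Genes were called at a q-value of 0.05 or less with test status OK. The 28 gene lists were fixed before the data were examined: Rac prophage, e14 prophage, Qin prophage, DLP12 prophage, SOS (LexA) regulon, flagella and chemotaxis, RpoS general stress, acid resistance, heat shock (sigma 32), envelope stress (Cpx, RpoE, Psp, Rcs), cold shock, ribosomal proteins, stationary-phase ribosome factors, TCA cycle and glyoxylate shunt, aerobic respiration and ATP synthase, anaerobic respiration and hydrogenases, arginine biosynthesis and transport, histidine biosynthesis, branched-chain amino acid biosynthesis, methionine biosynthesis, cysteine and sulfate assimilation, tryptophan and aromatic biosynthesis, purine and pyrimidine biosynthesis, iron acquisition (Fur), alternative sugar uptake and use, curli and fimbriae, toxin-antitoxin systems, and chromosomal restriction, modification and recombination. They hold 867 entries, of which 7 matched no gene name in the table. Each list was tested with Fisher's exact test, two-sided, for rises and for falls among tested genes, adjusted over 168 tests by Benjamini-Hochberg, and its median was placed among 10000 random lists matched in 20 bins of expression. The count adjusted over the list alone equalled the count over all genes in 61 of 84 cases and differed by at most 6; median and mean differed in sign in 7. Genes of 1 operon are not independent, so these tests describe the lists.

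Genes named in the text were chosen by a rule fixed at the same time: racR, ydaS, ydaT and every called Rac gene; per comparison the 10 called genes that rose most and fell most, with at least 10 FPKM in 1 of the groups, above 0 in both, and no rRNA or tRNA; up to 4 called members of each enriched list; and recA, lexA, sulA, hsdR, mcrA, mrr and the plasmid genes. The text gives the leading members of these sets, and a gene taken up in 1 comparison may be given in another. Other genes are said to be chosen after their values were seen. Coordinates are from the RefSeq annotation of ASM584v2, 1-based, to which 4430 genes matched by symbol or synonym. Of the genes, 1349 share a locus range with another gene, so reads between them are uncertain.

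Alternatives were q-values of 0.01 and 0.1, adjustment within each comparison, a minimum fold of 2, a mean of at least 5 FPKM, no status filter, centring on the median, pseudocounts of 1 and 5 on the FPKM, summed scaling, and 1 gene per run of neighbouring list genes. Normal p-values, genes alone in their locus and summed scaling of the calls' direction were added after the data were seen. The overlap of calls was set against 1000 simulations with no effect. The call rule with normal p-values was tested on simulated data for C-R+ against WT, 4314 genes with 200 changed. It recovered 15.9% of genes changed by 0.5, 68.7% by 1 and 89.4% by 2 on the log2 scale, with 4.81% false calls. The simulated noise had the same implied SDs that the rule used, which sets the share of false calls by construction. It therefore checks neither the SEs nor the deposited calls. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.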

Results

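RNA from 6 cultures of Escherichia coli MG1655, a K-12 laboratory strain, was sequenced after removal of ribosomal RNA. The cells carried the Csp231I restriction-modification system on a plasmid. Such a system pairs an endonuclease that cleaves a DNA sequence with a methyltransferase that protects it, and Csp231I also has a controller (C) protein that acts on transcription. The 3 groups were the complete system (WT), a variant with no endonuclease activity (C+R-) and a variant without the C gene (C-R+), with 2 biological replicates each. All strains held a second plasmid with an extra copy of the protective methyltransferase. The authors' deposited table gives 1 FPKM value per group for 4504 genes, so the spread between single libraries and the depth of each library are unknown. Levels, log2 fold changes and q-values given here are those of the authors' deposited table, and a gene was called at a q-value of 0.05 or less. The lowest q-value in the table was 0.000124. The implied SE beside a log2 fold change was obtained by dividing that value by the deposited test statistic, and all changes are given on the log2 scale.

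The plasmid genes come first because they bear on the labels of the groups. The C gene (plasmid positions 3981 to 4277) stood in the authors' deposited table at 2987 FPKM in WT, 2814 in C+R- and 1.67 in C-R+. Its log2 fold change in C-R+ against WT was -10.81 (implied SE 0.39, q = 0.000124), and in C+R- against WT, where it did not pass the test, it was -0.086 (implied SE 0.22, q = 0.662). The endonuclease gene was listed at 12515 FPKM in WT, 6689 in C+R- and 42368 in C-R+ and passed in no comparison, with 1.76 (implied SE 4.90, q = 0.233) in C-R+ against WT. RNA of the endonuclease gene does not show whether its product is active, so it does not check the C+R- label. The methyltransferase gene, whose reads can come from both plasmids, was listed at 8236 FPKM in WT, 11643 in C+R- and 11233 in C-R+ and passed in no comparison. The tetracycline resistance gene of the plasmid had a deposited log2 fold change of -1.19 (implied SE 0.27, q = 0.000124) in C-R+ and rose in C+R- by 0.79 (implied SE 0.37, q = 0.00999). The truncated beta-lactamase gene, at 39926 FPKM in WT, 31516 in C+R- and 49032 in C-R+, passed in no comparison. A hypothetical protein gene rose in C+R- against WT by 0.55 (implied SE 0.21, q = 0.000242).

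The series title names the repressor of the Rac prophage, a defective phage genome in the chromosome. Its gene racR (ASM584v2 chromosome, 1419765 to 1420241) was listed in the authors' deposited table at 124 FPKM in WT, 24.9 in C+R- and 480.4 in C-R+. It rose in C-R+ against WT by 1.95 (implied SE 0.19, q = 0.000124), and its log2 fold change in C+R- against WT was -2.32 (implied SE 0.19, q = 0.000124). The adjacent genes ydaS (1420365 to 1420661) and ydaT (1420684 to 1421106) moved the other way. The deposited level of ydaS was 293 FPKM in WT, 618 in C+R- and 10.2 in C-R+, and that of ydaT 124 FPKM in WT, 245 in C+R- and 6.19 in C-R+. In C-R+ against WT their log2 fold changes were -4.84 (implied SE 0.23) and -4.32 (implied SE 0.22), and in C+R- against WT they were 1.08 (implied SE 0.21) and 0.99 (implied SE 0.19). In the Rac list, 1 of 28 rose and 21 fell (median -3.80, exact adjusted p = 6.37e-05, 22 called when adjusted over the list alone) in C-R+ against WT. In C+R- against WT, 24 of 28 rose and 2 fell (median 0.89, exact adjusted p = 1.45e-10, 26 called when adjusted over the list alone). The p is from Fisher's exact test, two-sided, for the more frequent direction, with Benjamini-Hochberg adjustment over 168 tests of lists. The title was chosen on these samples, so the counts of this list are not independent evidence of their direction.

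Along the prophage the changes were uneven. The 12 tested genes from intR up to racR (between 1412000 and 1419456) all fell in C-R+ against WT in the authors' deposited table, with a median of -5.62, and all rose in C+R- against WT, with a median of 1.00. In C-R+ against WT the inhibitor of cell division kilR stood at -6.16 (implied SE 0.39), ydaC at -6.23 (implied SE 0.87) and ralR at -6.07 (implied SE 0.80). There racC stood at -5.75, the superinfection exclusion gene sieB at -4.74 and the recombination genes recE and recT at -4.38 and -4.01. In C+R- against WT kilR, ydaC, ralR, racC, sieB, recE and recT stood at 1.49 (implied SE 0.21), 0.95, 0.97, 0.70, 1.68, 1.13 and 0.89. From ydaS to ydaW the medians of C-R+ and C+R- against WT were -4.32 and 0.90 over 5 genes. The next 4 tested genes, including the potassium transporter gene trkG (-0.83 and 1.35), had medians of -1.37 and 1.05. At the right end, from tmpR to ynaE (1426454 to 1434224), 0 of 6 genes were called in C-R+ against WT (median 0.14). In C+R- against WT, 3 of these rose and 1, ynaE, stood at -1.28 (implied SE 0.25). These parts were drawn after the values were seen. Some Rac genes overlap a neighbour, such as ydaC and ralR or recE and recT, so their single values are uncertain. The levels of ydaC and ralR in C-R+ were also only 0.710 and 0.552 FPKM. Counting 1 gene per run of neighbours, the member of highest level, left 4 Rac runs. Of these 2 fell in C-R+ against WT, which was no longer an enrichment (exact adjusted p = 0.917). The run that holds racR was represented there by racR itself, the 1 Rac gene that rose. This count therefore says nothing about the falls of the other genes of that run.

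**Figure D1:**
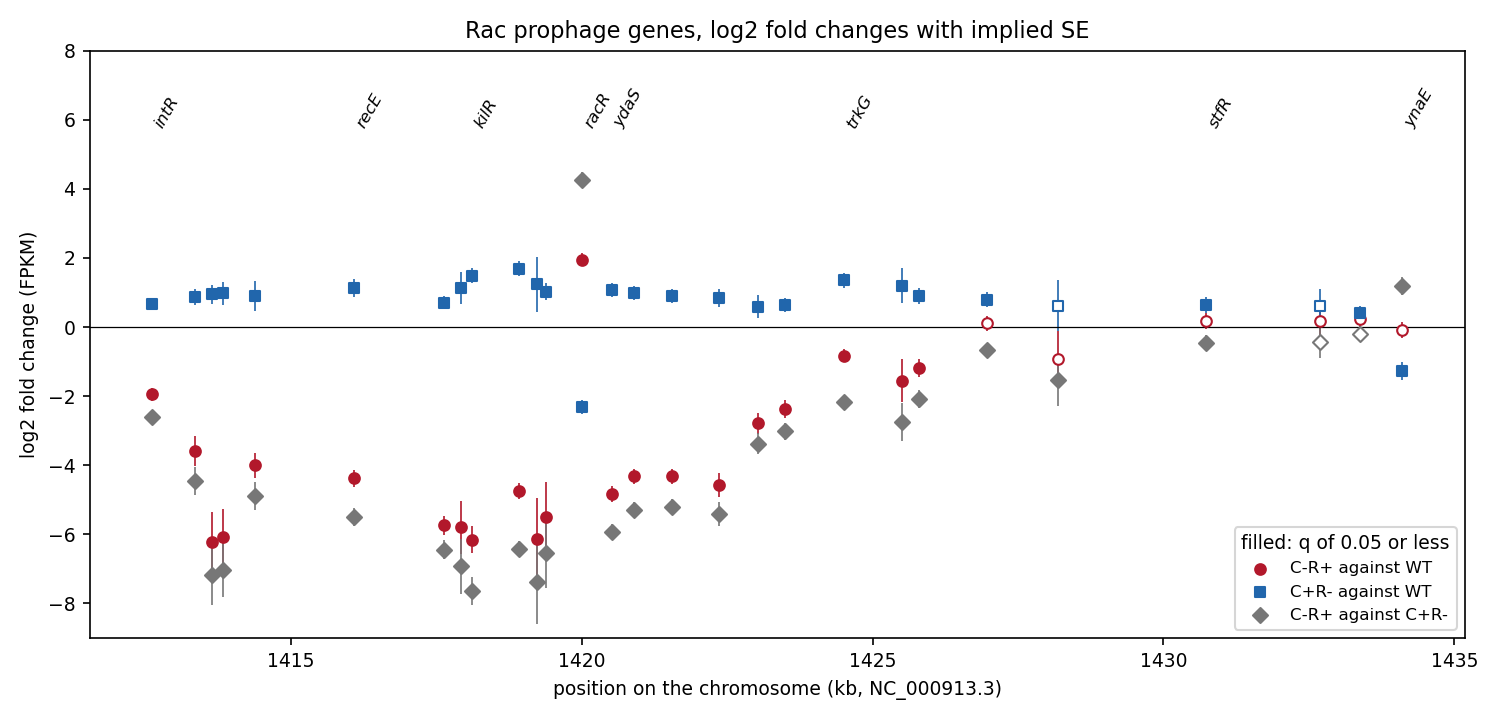
Log2 fold change of each tested Rac prophage gene (y axis) by its position on the chromosome in kb (x axis) for the 3 comparisons, where points are the deposited values, bars the implied SE, and filled points passed a q-value of 0.05. The genes left of racR lie below 0 in C-R+ against WT and above 0 in C+R- against WT, and racR lies at 1.95 and -2.32.

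The comparison of C-R+ with WT asks what differs in cells without the C gene. All 50 tested iron acquisition genes fell in the authors' deposited table (median -3.21, Fisher's exact test, adjusted p = 7.87e-23, 50 called when adjusted over the list alone). Among them were the siderophore receptor gene fiu at -5.54 (implied SE 0.23) and the enterobactin genes entB at -5.31 (implied SE 0.54) and entS at -4.90 (implied SE 0.47). The ferric citrate transporter gene fecC stood at -4.89 (implied SE 0.72). In WT entB, entS and fecC were listed at only 17.9, 7.38 and 7.29 FPKM. In C-R+ they were listed at 0.449, 0.246 and 0.246 FPKM, so the sizes of these falls are uncertain. Of the flagella and chemotaxis list, 44 of 53 rose and 1 fell (median 1.79, exact adjusted p = 3.68e-12, 46 called when adjusted over the list alone). The ribose and galactose receptor gene trg rose by 3.92 (implied SE 0.20), the anti-sigma factor gene flgM by 3.76 (implied SE 0.20), the aerotaxis receptor gene aer by 3.65 and flgN by 3.54. The flagellin gene fliC was listed at 552 FPKM in WT and 14382 in C-R+ and did not pass, at 4.70 (implied SE 2.30, q = 0.213). Of the SOS (DNA damage) regulon, 2 of 30 rose and 25 fell (exact adjusted p = 4.33e-07, 27 called when adjusted over the list alone). The recombinase gene recA (2822708 to 2823769) stood at 1365 FPKM in WT, 1529.6 in C+R- and 457 in C-R+, and its log2 fold change in C-R+ against WT was -1.58 (implied SE 0.24). The SOS repressor gene lexA stood at 619 FPKM in WT, 603 in C+R- and 106 in C-R+, at -2.54 (implied SE 0.19) in C-R+ against WT, with ydjM at -2.58, recX at -2.33 and dinF at -2.32. The cell division inhibitor gene sulA of this regulon did not pass (-0.17, implied SE 0.21, q = 0.312).

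Sulfur genes were among the steepest rises of C-R+ against WT in the authors' deposited table. Of the cysteine and sulfate list, 16 of 26 rose and 2 fell (median 3.40, exact adjusted p = 0.00999, 18 called when adjusted over the list alone). The sulfate adenylyltransferase gene cysD rose by 7.06 (implied SE 0.25), the thiosulfate-binding protein gene cysP by 6.97 (implied SE 0.34), the cysteine synthase gene cysK by 6.04 (implied SE 0.83) and the sulfate-binding protein gene sbp by 5.97 (implied SE 0.22). Outside the list, yeeD and yeeE rose by 6.65 and 6.43, and ygeW by 6.75. The tryptophanase gene tnaA rose from 208 to 19622 FPKM, by 6.56 (implied SE 4.32, q = 0.0287), and the tryptophan transporter gene tnaB by 6.08. Of the acid resistance list, 14 of 21 rose and 5 fell (median 1.10, exact adjusted p = 0.00733, 20 called when adjusted over the list alone). The periplasmic chaperone genes hdeB and hdeA rose by 6.20 (implied SE 0.22) and 5.88 (implied SE 0.22), slp by 4.95 and the activator gene gadE by 3.77. Of the list for the TCA cycle and glyoxylate shunt, 17 of 21 rose and 1 fell (median 2.16, exact adjusted p = 6.47e-05, 18 called when adjusted over the list alone). Its leading members were sdhC at 4.74, aceB at 4.44, sdhD at 4.18 and gltA at 4.14. Of the RpoS (general stress) list, 24 of 38 rose and 9 fell (median 1.18, exact adjusted p = 0.00092, 33 called when adjusted over the list alone). These included ugpB at 3.64, csiD at 3.49, dps at 2.91 and treA at 2.16. Of the heat shock list, 14 of 24 rose and 3 fell (median 0.62, exact adjusted p = 0.0373, 17 called when adjusted over the list alone). The chaperone genes dnaK and groS rose by 2.61 (implied SE 1.01) and 2.21, ibpA by 2.11 and fxsA by 2.05. The heat shock median lay at percentile 52.44 of 10000 random lists matched by expression, and it was 0.061 under summed scaling, which is described below. In each of the other enrichments reported in the 3 comparisons, the median lay at percentile 98.67 or higher for rises and 1.755 or lower for falls.

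Nucleotide and histidine genes were lower in C-R+ than in WT in the authors' deposited table. Of the purine and pyrimidine list, 3 of 31 rose and 18 fell (median -0.50, exact adjusted p = 0.0178, 21 called when adjusted over the list alone). Falls were read for pyrF at -2.37, guaA at -2.03, guaB at -1.78 and carA at -1.67. Of the histidine list, whose genes share an operon, 0 of 9 rose and 7 fell (median -1.44, exact adjusted p = 0.0232, 7 called when adjusted over the list alone). Falls there included hisC at -2.25 (implied SE 0.84), hisH at -1.95 (implied SE 0.85), hisA at -1.95 (implied SE 0.78) and hisD at -1.52 (implied SE 0.77). These were low already in WT, at 5.28, 8.08, 7.94 and 4.10 FPKM. Outside the lists enriched in this comparison, the glycerol-3-phosphate dehydrogenase genes glpA and glpD stood at -7.68 (implied SE 0.43) and -5.85 and the nitrite reductase gene nirB at -6.70 (implied SE 0.23). In all, 2920 of 4357 tested genes were called, 1451 higher and 1469 lower in C-R+, of which 811 and 780 were at least 2-fold. Scaling the groups to their summed FPKM without rRNA, tRNA and the 10 highest genes moved every log2 fold change by -0.56. By the sign of the moved values, 1233 of the 2920 calls were then higher and 1687 lower. These are the deposited calls, not tested again after scaling. The rRNA genes made up 0.0493% of the summed FPKM in WT and 1.48% in C-R+. With 1 gene per run of neighbours the enrichments of cysteine (exact adjusted p = 0.149), TCA cycle (0.271), acid resistance (0.0873), purine (0.295), histidine (0.665) and heat shock genes (0.145) ended. A mean of at least 5 FPKM also ended those of acid resistance (exact adjusted p = 0.0567), purine (0.302), histidine (0.107) and heat shock genes (0.175), a minimum fold of 2 those of purine (0.0569) and heat shock genes (0.239), and a q-value of 0.01 those of histidine (0.0555) and heat shock genes (0.0956), the last also at 0.1 (0.065).

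The comparison of C+R- with WT asks what differs where the C gene is kept and the endonuclease is inactive. Of the flagella and chemotaxis list, 51 of 53 rose and 0 fell (median 1.56, exact adjusted p = 3.35e-28, 52 called when adjusted over the list alone) in the authors' deposited table. The serine receptor gene tsr rose by 4.40 (implied SE 0.20), the chemotaxis genes cheB, cheZ and cheY by 3.46, 3.33 and 3.13, the motor gene motA by 3.25, fliC by 3.22 (implied SE 0.52) and tar by 3.16. Outside the list, yhjH, a cyclic-di-GMP phosphodiesterase gene, rose by 3.88, and the serine deaminase and serine transporter genes sdaB and sdaC by 3.21 and 3.12. Of the iron acquisition list, 0 of 50 rose and 48 fell (median -1.89, exact adjusted p = 4.11e-27, 48 called when adjusted over the list alone). The lowest were feoA at -4.06, entB at -3.42, fiu at -3.23 and fepA at -3.14. Of the RpoS list, 1 of 38 rose and 27 fell (median -1.18, exact adjusted p = 8.41e-09, 29 called when adjusted over the list alone). Its leading members were wrbA at -3.74, ycgB at -2.34, yjbJ at -1.95 and elaB at -1.89. Of the anaerobic respiration list, 4 of 57 rose and 24 fell (median -0.46, exact adjusted p = 0.00465, 28 called when adjusted over the list alone). The nitrite reductase gene nirB stood at -5.40 (implied SE 0.23), the nitrate reductase gene narG at -4.68 (implied SE 0.24), the nitrate transporter gene narK at -4.39, dmsA at -4.27 and napF at -4.13. In C-R+ against WT, 3 of this list rose and 25 fell (28 called when adjusted over the list alone), and the falls were not enriched (exact adjusted p = 0.204). The list was low there too, with a median of -0.73 at percentile 0.24 of random lists matched by expression. The same genes nirB, narG, narK, dmsA and napF stood there at -6.70, -5.71, -4.50, -2.56 and -4.36.

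Smaller rises in C+R- were found in lists for protein quality, nucleotides and respiration in the authors' deposited table. Of the heat shock list, 15 of 24 rose and 0 fell (median 0.43, exact adjusted p = 0.000275, 15 called when adjusted over the list alone). These included fxsA at 1.64, ibpA at 1.46, htpX at 1.11 and dnaJ at 1.02. Of the purine and pyrimidine list, 16 of 31 rose and 0 fell (median 0.36, exact adjusted p = 0.00349, 15 called when adjusted over the list alone). Rises were read for pyrE at 1.15, pyrF at 0.98, purB at 0.75 and purM at 0.67. Of the list for aerobic respiration and ATP synthase, 14 of 30 rose and 4 fell (median 0.39, exact adjusted p = 0.0129, 18 called when adjusted over the list alone). Its leading members were atpI at 1.02, atpB at 0.97, cyoA at 0.87 and atpH at 0.83. Falls were enriched in the list of alternative sugars, where 21 of 77 rose and 34 fell (median -0.20, exact adjusted p = 0.000171, 56 called when adjusted over the list alone). The lowest were glpA at -5.47, glpB at -3.53, srlD at -3.16 and srlB at -2.77. Of the toxin-antitoxin list, 3 of 36 rose and 19 fell (median -0.56, exact adjusted p = 0.000465, 23 called when adjusted over the list alone). These included ghoS at -4.10, ghoT at -2.47, higB at -1.63 and higA at -1.45. Of the acid resistance list, 1 of 21 rose and 11 fell (median -0.38, exact adjusted p = 0.00999, 12 called when adjusted over the list alone). Falls were read for adiY at -2.01, gadX at -1.70, gadE at -1.21 and hdeD at -0.71. Of the cold shock list, 0 of 15 rose and 8 fell (median -0.87, exact adjusted p = 0.0252, 8 called when adjusted over the list alone). Its leading members were cspG at -3.04, raiA at -2.48, cspA at -2.35 and lpxP at -1.38. Outside the enriched lists ysaA stood at -4.76, yjjI at -4.76, bssR at -4.36 and yhbU at -4.20.

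In all, 2018 of 4369 genes tested in C+R- against WT were called in the authors' deposited table, 1021 higher and 997 lower, of which 223 and 354 were at least 2-fold. Summed scaling moved the log2 fold changes of this comparison by -0.068, and rRNA genes made up 1.21% of the summed FPKM in C+R-. With 1 gene per run of neighbours the enrichments of sugar (exact adjusted p = 0.162), toxin-antitoxin (0.121), acid resistance (0.73), aerobic respiration (0.151) and heat shock genes (0.0502) ended. A minimum fold of 2 ended those of heat shock (exact adjusted p = 0.0837), purine (1), aerobic respiration (1) and acid resistance genes (0.419), a mean of at least 5 FPKM those of acid resistance (0.0562), aerobic respiration (0.0567) and cold shock genes (0.0785), a q-value of 0.01 those of acid resistance (0.0888) and purine genes (0.117), and a q-value of 0.1 that of cold shock genes (0.0668).

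The variants were also compared with each other, which tests the difference between their effects. General stress genes were higher in C-R+ than in C+R- in the authors' deposited table, where of the RpoS list 31 of 38 rose and 3 fell (median 1.85, exact adjusted p = 6.84e-08, 34 called when adjusted over the list alone). Rises were read for wrbA at 4.59, dps at 4.25, ycgB at 4.24 and yjbJ at 3.94. Of the acid resistance list, 16 of 21 rose and 4 fell (median 1.39, exact adjusted p = 0.000653, 20 called when adjusted over the list alone). The genes hdeB and hdeA rose by 6.85 (implied SE 0.23) and 6.38, slp by 5.38 and gadE by 4.98. Of the list for the TCA cycle, 18 of 21 rose and 1 fell (median 1.88, exact adjusted p = 1.68e-05, 19 called when adjusted over the list alone). These included gltA at 3.77, sdhC at 3.63, sdhD at 3.26 and mdh at 3.15. Of the cysteine and sulfate list, 16 of 26 rose and 3 fell (median 3.10, exact adjusted p = 0.0175, 20 called when adjusted over the list alone). Its leading members were cysD at 6.45, cysK at 6.42, cysP at 6.27 and sbp at 6.15. The gene bsmA, at 15.5 FPKM in C+R- and 1627 in C-R+, rose by 6.72 (implied SE 0.22), and tnaA rose by 7.83 (implied SE 4.32, q = 0.0252). The ferrous iron transport gene feoA was higher in C-R+ than in C+R- by 3.30 (implied SE 0.21).

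Rac prophage, DNA repair, nucleotide and iron genes were lower in C-R+ than in C+R- in the authors' deposited table. Of the Rac list, 2 of 28 rose and 24 fell (median -4.68, exact adjusted p = 1.32e-06, 26 called when adjusted over the list alone). The genes kilR, ydaF and ydaG stood at -7.64 (implied SE 0.40), -7.38 and -6.53, and racR at 4.27 (implied SE 0.21). Of the SOS regulon, 3 of 30 rose and 23 fell (median -1.60, exact adjusted p = 6.37e-05, 26 called when adjusted over the list alone). Among its genes were umuC, a subunit of an error-prone DNA polymerase, at -3.08 (implied SE 0.27), ydjM at -3.13, and the repair genes uvrD and uvrA at -2.66 and -2.64. Of the purine and pyrimidine list, 3 of 31 rose and 24 fell (median -0.99, exact adjusted p = 3.37e-05, 28 called when adjusted over the list alone). The lowest were pyrF at -3.35, guaB at -2.37, guaA at -2.20 and carA at -1.99. Of the iron acquisition list, 4 of 50 rose and 40 fell (median -1.27, exact adjusted p = 1.01e-08, 45 called when adjusted over the list alone). Falls were read for nrdI at -3.32, fhuC at -2.71, entS at -2.64 and efeU at -2.61. The flagella and chemotaxis list had 18 rises and 19 falls among 53 genes (37 called when adjusted over the list alone), and neither direction was enriched (exact adjusted p = 1 for both). Its median was 0.039, or -0.45 under summed scaling. The pyruvate transporter gene yjiY stood at -6.08 (implied SE 0.23). In all, 3108 of 4363 tested genes were called, 1517 higher and 1591 lower in C-R+, of which 939 and 908 were at least 2-fold. Summed scaling moved these log2 fold changes by -0.49. By the sign of the moved values, 1361 of the same calls, not tested again, were higher and 1747 lower. With 1 gene per run of neighbours the enrichments of Rac (exact adjusted p = 0.357), acid resistance (0.106), TCA cycle (0.149), cysteine (0.228) and iron genes (0.0549) ended.

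**Figure D2:**
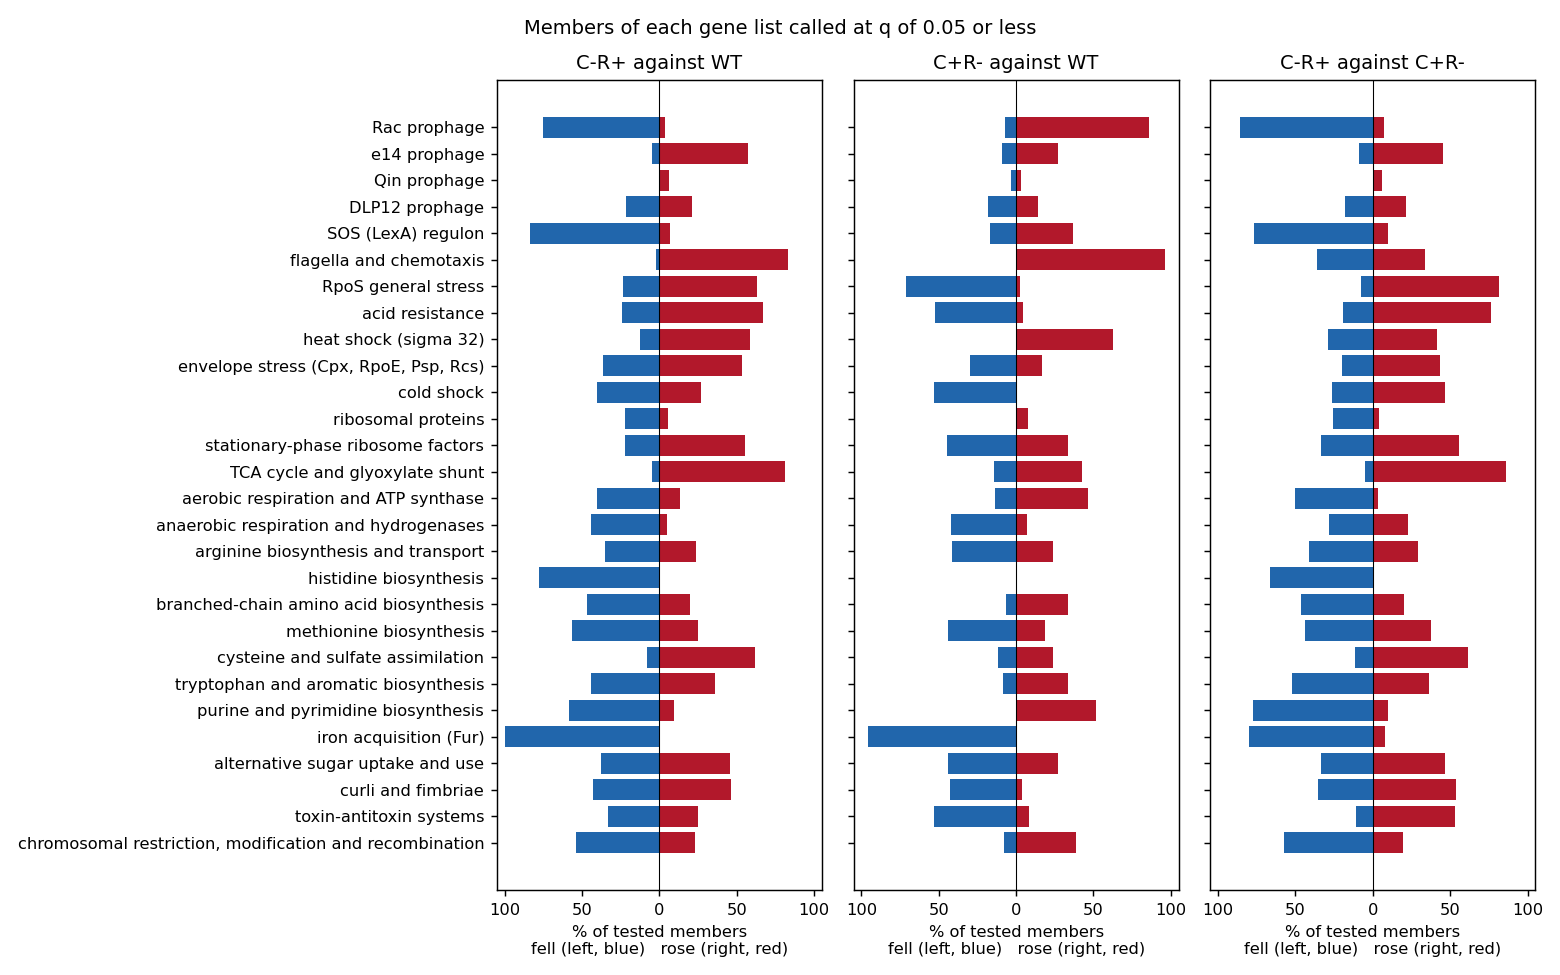
Percent of the tested members of each of the 28 gene lists (x axis, rises to the right and falls to the left) that passed a q-value of 0.05, for each list (y axis) in the 3 comparisons. Iron acquisition genes fell in 50 of 50 cases in C-R+ against WT and 48 of 50 in C+R- against WT, and the RpoS list holds 24 rises in the first of these comparisons and 27 falls in the second.

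The other lists were enriched in no comparison by Fisher's exact test, the lowest exact adjusted p for an excess being 0.0506 (curli and fimbriae falls in C+R- against WT, 12 of 28). Some medians still lay at the ends of the random lists matched by expression. The e14 median was 1.13 (percentile 100) in C-R+ against WT and 0.82 (99.95) in C-R+ against C+R-. In C-R+ against WT the stationary-phase ribosome factors had 1.62 (percentile 99.1) and the ribosomal proteins -0.11 (percentile 0). Rises and falls in C-R+ against WT in the authors' deposited table were 12 and 1 of 21 (13 called when adjusted over the list alone) for the e14 prophage, 2 and 0 of 33 (2 called when adjusted over the list alone) for the Qin prophage and 6 and 6 of 28 (11 called when adjusted over the list alone) for the DLP12 prophage. They were 16 and 11 of 30 (27 called when adjusted over the list alone) for envelope stress, 13 and 12 of 28 (27 called when adjusted over the list alone) for curli and fimbriae, and 5 and 2 of 9 (7 called when adjusted over the list alone) for the stationary-phase ribosome factors. Amino acid lists had 4 and 6 of 17 (10 called when adjusted over the list alone) for arginine, 3 and 7 of 15 (10 called when adjusted over the list alone) for branched-chain amino acids, 4 and 9 of 16 (13 called when adjusted over the list alone) for methionine, and 9 and 11 of 25 (20 called when adjusted over the list alone) for tryptophan and aromatic amino acids. Ribosomal protein genes had 3 and 12 of 54 (9 called when adjusted over the list alone), with fewer rises than other genes (Fisher's exact test, adjusted p = 1.37e-05). The Qin prophage had both fewer rises and fewer falls than other genes (exact adjusted p = 0.00149 and 1.68e-05), and the e14 prophage fewer falls (exact adjusted p = 0.0118). Fisher's exact test does not match genes by expression, while the median implied SD in WT was 0.478 below 1 FPKM and 0.146 at 10 to 100 FPKM. Whether these low counts reflect only how readily genes of their level pass was not tested. For chromosomal restriction, modification and recombination genes the counts were 6 and 14 of 26 (20 called when adjusted over the list alone). The restriction gene hsdR stood at 40.6 FPKM in WT, 29.4 in C+R- and 64 in C-R+, rising in C-R+ against WT by 0.66 (implied SE 0.21, q = 0.000242). The restriction gene mcrA, at 19.9 FPKM in WT, 20.4 in C+R- and 24.9 in C-R+, rose in C-R+ against WT by 0.32 (implied SE 0.20, q = 0.0413) and turned to -0.23 under summed scaling. The deposited levels of mrr, another restriction gene, were 50.7 FPKM in WT, 47.2 in C+R- and 48.1 in C-R+, and it passed in no comparison. Across the 84 cases of a list in a comparison, summed scaling turned the sign of 14 medians, in none of which an enrichment is reported.

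The calls of both variants against WT were set side by side. Over 4349 genes tested in both comparisons of the authors' deposited table, 359 rose in both and 354 fell in both. Independent lists of these sizes would share 339 and 337, and 1000 simulations with no effect and shared WT values gave 68.4 and 68.2 on average. The simulations called genes beyond a fixed test statistic of 1.54, without adjustment. Their counts are therefore not those expected for lists of the observed sizes. Another 451 genes rose in C-R+ and fell in C+R-, and 429 did the reverse, against 332 and 344 for independent lists. With a minimum fold of 2, 246 genes changed in the same direction and 122 in opposite directions, against 104 in the same direction for independent lists. Across 4314 genes, which are not independent replicates, the correlation of the fold changes was 0.14 (simulated mean 0.37) and the covariance 0.182 (simulated mean 0.42). Over 4159 genes of implied spread under 1, a set chosen after the simulated values were seen, the covariance was 0.185 (simulated mean 0.0515), so the simulated means over all genes depend on genes of large spread. Part of any excess may come from the shared WT libraries, which could not be split between the comparisons because the table gives 1 value per group.

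**Figure D3:**
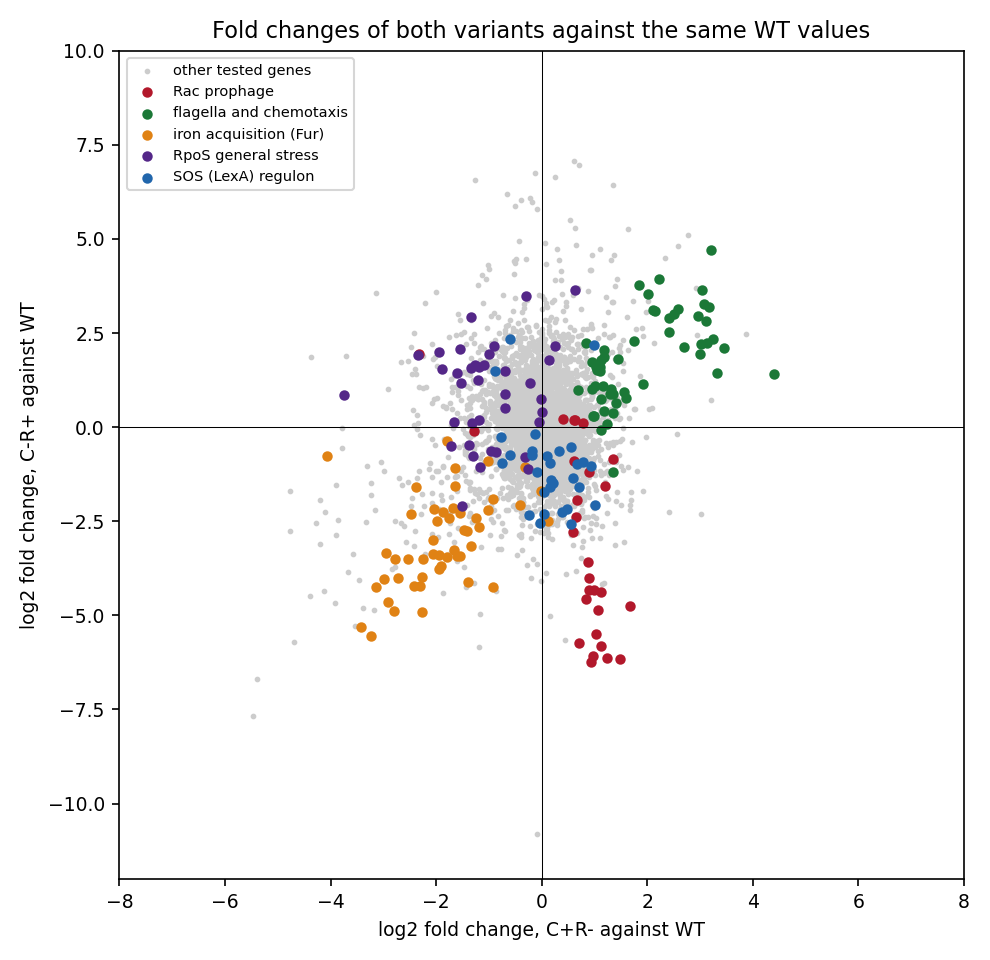
Log2 fold change in C+R- against WT (x axis) and in C-R+ against WT (y axis), both from the deposited table, with gene lists in colour. The 4297 genes drawn were tested in both comparisons. Genes listed at 0 in a group and rRNA genes were left out. Of the iron list 50 and 48 genes fell in C-R+ and C+R-, of the flagella list 44 and 51 rose, and Rac genes lie mostly at the lower right, below 0 in C-R+ and above 0 in C+R-.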

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

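All tests of explanations in this part were chosen after the results were seen. Genes that moved in opposite directions in the variants are given here because the difference between the variants has a comparison of its own. Both directions are read against the same WT value, so such genes must differ between the variants, and being called there adds no support. There were 451 genes higher in C-R+ and lower in C+R- than in WT in the authors' deposited table that were also called between the variants, among them 17 of 38 RpoS and 9 of 21 acid resistance genes. The reverse held for 429 genes, among them 21 of 28 Rac and 11 of 30 SOS genes.

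The Rac genes fell in C-R+ while racR rose. Loss of the prophage from C-R+ cells would lower all its genes alike, but racR, which lies inside it, rose to 480.4 FPKM. The genes at the right end of the prophage had a median log2 fold change of 0.14. That part was drawn after the values were seen, so its median adds little. Reads shared out wrongly between overlapping genes are argued against by the 11 tested Rac genes other than racR that are alone in their locus, called or not, whose median was -3.59. The order of levels C+R-, WT, C-R+ from high to low, opposite to racR, was found in 22 of 27 other tested Rac genes. This restates the counts of rises and falls, so it does not test whether RacR lowers these genes, which stays open. The amount of C RNA alone is argued against for the low racR level in C+R-, because the C gene differed there by -0.086 on the log2 scale (implied SE 0.22); C protein was not measured and stays open.

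Flagellar genes were higher and iron genes lower in both variants than in WT, and the anaerobic list had medians of -0.73 and -0.46 in C-R+ and C+R- against WT. A state of the WT cultures alone, such as their growth phase, could give this, and would leave the variants alike. The iron list was not alike, with a median of -1.27 in C-R+ against C+R-, where 40 of 50 fell and 4 rose, feoA by 3.30. This argues against a WT state only as the whole cause of the falls in C-R+. With 1 gene per run of neighbours 11 of 16 iron genes fell there, and the falls were no longer enriched (exact adjusted p = 0.0549), so this rests on the median and the counts. A WT state can still give the fall that both variants share, which C-R+ against C+R- does not test. The flagellar median of 0.039 there (-0.45 under summed scaling) decides nothing, since 18 members rose and 19 fell, and the anaerobic median of -0.29 is large beside -0.46 in C+R- against WT, but the falls were not enriched there (exact adjusted p = 0.323) and it lay at percentile 65.9 of random lists matched by expression, so for these lists they cannot be told apart. Chance spread of the shared WT values was not excluded over all genes, where the observed covariance was 0.182 and simulated ones ranged from -2.07 to 2.88, wider than the largest possible value of 1.28; over 4159 genes of implied spread under 1, chosen after that range was seen, it was 0.185 against a simulated highest of 0.0624.

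In C-R+ against WT 67.0% of tested genes were called. Deposited p-values smaller than the test statistics give may add to this, but 83.7% of the calls passed with normal p-values, so they do not account for the share. With normal p-values summed scaling gave 111% as many calls as before. The deposited median log2 fold change was already -0.050, and this scaling shifts every gene by -0.56, away from 0 for most. It could hardly lower the calls, so it does not decide whether the scaling of the groups adds to the share. Standard errors set by expression level rather than by each gene's own replicates remain open: level explained 38.9% of the variance of the log implied SD in the lowest of the groups, and 68.6% to 71.2% among genes alone in their locus. That second set of genes was added after the first value was seen. The difference between the groups in the C gene and the endonuclease stays among the open explanations, as untested. A difference between the groups in their cultures or library preparation cannot be told apart from it here and was not tested either. The rRNA left after depletion did differ. Median 16S values were 52.6 FPKM in WT, 2065 in C+R- and 199 in C-R+, and median 5S values 0.988, 0.574 and 2567.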

How the results depend on the processing

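Alternatives with normal p-values, with genes alone in their locus and with summed scaling of the calls' direction were chosen after the data were seen. No paired analysis was possible because the deposited table holds 1 value per group; for the same reason the limma fits and the omission of each replicate were not run. A minimum fold of 2 left 1591 calls in C-R+ against WT, 577 in C+R- against WT and 1847 between the variants, 11 Rac calls in C+R- against WT and 246 genes called in the same direction in both variants. With a pseudocount of 1 and a minimum fold of 2 the calls were 1386, 511 and 1600, with 10 Rac calls in C+R-. These settings remove small changes by construction. Among Rac genes alone in their locus 9, 12 and 11 were called, since fewer were tested. Normal p-values gave 2447, 1398 and 2612 calls in C-R+ against WT, C+R- against WT and between the variants, within 1.5 times the reported counts. They kept 83.7%, 69.3% and 83.9% of the reported calls, so the calls of C+R- against WT depended on them most. With 1 gene per run of neighbours 16 list enrichments passed in place of 31, fewer genes being tested, and 14 of the reported ones were kept; 27 were kept at a q-value of 0.01, 29 at 0.1, 25 at a minimum fold of 2 and 24 at a mean of 5 FPKM. Of 465 fold changes of named genes, 5 called ones reversed under summed scaling, which shifts them by construction: cyoA to -0.022 (C-R+ against C+R-), fxsA to -0.077 (C-R+ against C+R-), gadX to -0.069 (C-R+ against WT), htpX to -0.076 (C-R+ against WT) and mcrA to -0.23 (C-R+ against WT). Pseudocounts and centring reversed 0. A pseudocount cannot turn a sign, by construction. It shrinks the folds of genes at low levels, and that change in size was not counted here. Depth is unknown, so what it limits cannot be given.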

Other observations

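The genes and groups in this paragraph were chosen after their values were seen, and no enrichment was tested. For C-R+ against WT in the authors' deposited table, 12 of 14 genes of dipeptide and glutathione uptake rose (median log2 fold change 2.06), including dppA at 4.42 (implied SE 0.26) and gsiB at 3.18; the oligopeptide-binding gene oppA rose by 2.71. Of 7 universal stress protein genes 6 rose in C-R+ and 7 fell in C+R- against WT, with uspA at 1.43 (implied SE 0.23) and -1.41 (implied SE 0.21) and uspG at 1.67 and -1.11. Of 13 genes of thiamine synthesis and salvage 9 fell in C-R+ (thiC at -1.47) and 6 rose in C+R-. Falls in C-R+ were counted for 5 of 5 molybdopterin genes (moaA at -2.20), 4 of 6 nickel uptake genes (nikA at -3.84) and 10 of 15 genes of phosphate and phosphonate uptake (pstS at -0.93).

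The ribosomal RNA genes, targets of the depletion, are counted among the tested and called genes of the comparisons, though the rule for named genes left them out. The 8 5S genes had a median log2 fold change of 11.35 in C-R+ against WT (medians of 0.988 and 2567 FPKM in the deposited table), and the 7 16S genes one of 5.29 in C+R- against WT (medians of 52.6 and 2065 FPKM). The copies are near-identical, so their reads are shared. In C+R- against WT the 5S median was -0.90.

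Small RNAs were also chosen after their values were seen. They are short, as is the 5S rRNA, which was higher in C-R+ than in WT by a median of 11.35. The recovery of short RNAs was not compared between the libraries, so whether these genes differ in the cells is not shown. The small RNA csrC of the authors' deposited table, which binds the carbon storage regulator CsrA, rose in C-R+ against WT by 1.13 (implied SE 0.41), while csrB, with the same function, was listed at 33525 FPKM in WT, 30438 in C+R- and 138358 in C-R+ and did not pass, at 2.05 (implied SE 4.79, q = 0.189). The small RNA sgrS, made under sugar-phosphate stress, stood at 129 FPKM in WT, 30.8 in C+R- and 452 in C-R+, with log2 fold changes of 1.81 (implied SE 0.20) and -2.07 (implied SE 0.21) in C-R+ and C+R- against WT. The tmRNA gene ssrA, the highest in WT, was listed at 162201 FPKM in WT, 166882 in C+R- and 496305 in C-R+ and did not pass in C-R+ against WT, at 1.61 (implied SE 4.61, q = 0.258).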
